A study of Mus musculus with 8 samples.

How the data were processed

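The series holds 8 mouse RNA-seq libraries in 4 groups of 2. The groups are induced pluripotent stem (iPS) clones made with Oct4, Klf4 and Sox2 (3F) and given IL6 at 10 ng/mL, iPS clones made with 4 factors (4F), D3-GFP embryonic stem (ES) cells, and mouse embryonic fibroblasts (MEF). Per the labels, the clones of each kind were derived independently, and the ES and MEF libraries are biological replicates. The ES cells are of the 129S2/SvPas background and all other samples are BALB/c, so strain and cell type change together in every comparison with ES cells. Per the labels' protocols, poly-A RNA was selected with oligo-dT beads from 500 ng of total RNA, and libraries were made with the TruSeq mRNA kit and sequenced as 50 bp reads. Reads were aligned to mm10, per the submitters' processing notes. The aligner, the counting tool, the gene models and the handling of reads that map to several places are not given in the sources used here.

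Each library's deposited table lists 23389 gene symbols with a single value. No header names the unit. The deposited values were read as RPKM (reads scaled to gene length and to the reads of the library), because low values of genes with a single transcript, multiplied by transcript length, cluster at multiples of a step that is constant within a library. Only 42.7% to 48% of the low values were whole within 0.1 read, so read counts were not recovered and no count test was run. The step gave an estimated depth of 15700000 and 14900000 reads for ES, 13400000 and 14200000 for 3F+IL6, 11800000 and 12500000 for 4F, and 17800000 and 18200000 for MEF.

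From these values, log2(RPKM + 1) was computed and genes with an RPKM of at least 1 in at least 2 samples were kept, which left 13200 genes; 3911 symbols were at 0 in every library. A fold change on this scale understates the change of genes with low values. limma 3.58.1 in R 4.3.3 fitted all 8 samples in a single model with trended empirical Bayes variance and no replicate block. Each of 6 comparisons was adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The median standard error of a log2 difference was 0.102, with 6.94 degrees of freedom. The statements "called", "higher", "lower", "rose" and "fell" refer to this test. The groups, the tests, the gene lists, the rule for naming genes and the first set of alternative settings were fixed before the data were examined.

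Of 30 gene lists, the 29 with at least 3 measured members were tested with camera from limma at an inter-gene correlation of 0.01, two-sided, with adjustment over all 174 tests. camera called 60 of the 174. With an estimated correlation it called 0, the smallest adjusted p being 0.4, while 16 tests had an unadjusted p under 0.05. In that setting camera gave adjusted p = 0.4 for the pluripotency network in ES against MEF, where all 28 genes rose with a median of 5.54. A value over the threshold there therefore does not show that a list is unshifted. fry called 123 for a shift to a single side and 158 for change in either direction. fry asks whether the genes of a list move, not whether they move more than other genes. The list written as all symbols that begin with Rpl or Rps also takes in Rps6k kinases and some pseudogenes.

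Genes were named by a fixed rule: the 6 largest changes in each direction among called genes whose groups did not overlap and whose higher group had a mean of at least 5, the 4 reprogramming factors, and up to 4 members with the smallest p from each list described. Unnamed predicted genes were left out of the largest changes, and 4F against MEF and ES against MEF name only genes named for 3F+IL6 against MEF. Any member of the Dlk1-Dio3, MYC family, IL6 pathway and sex chromosome lists could be named. Genes outside the rule and chosen after their values were seen are Dnmt3b, Esx1, Fosl1, Des and Actc1 between the kinds of clone. Ddit4, Bnip3, Rn45s, Rpph1 and Rmrp were also chosen that way. The other 14 low-oxygen targets are outside the rule too, but were fixed before their values were seen. A gene that the rule names is not reported here.

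Coordinates are mm10 from GENCODE release M21, 1-based. Of the symbols, 20987 matched a GENCODE symbol, 241 a RefSeq symbol and 1893 a RefSeq synonym; 268 were unmatched. Of the deposited symbols, 25 had been turned into dates and were not renamed. Reads shared between near-identical genes, pseudogenes or antisense partners were not resolved here, so single histone, ribosomal protein and Xist or Tsix values carry that uncertainty.

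The fit was tested on simulated data for 3F+IL6 against 4F over 13200 genes. With the same spread in all groups, it recovered 44.6%, 92.5% and 98.8% of genes changed by 0.5, 1 and 2 log2 units, and 4.79% of calls were false. A further simulation pooled the spread of ES with MEF and that of 3F+IL6 with 4F. There, 32.5% of the calls were false in the fit of 8 samples and 8.58% in a fit of the 4 samples compared. Each of these simulations changed 200 genes, and the share of false calls depends on that number. The unequal spread of 3F+IL6 and 4F was not simulated. A list of MYC targets shifted by 0.5 was found in 20 of 20 simulations, and 4.11% of unshifted lists had a p under 0.05. The noise of each gene was drawn independently, so these simulations cannot show how correlation between genes affects camera.

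Alternatives were median centring, quantile normalization, no filter, a mean of at least 5, limma without trend, a pseudocount of 0.1, the replicate number as a block, only the 4 samples compared, each library left out in turn, an absolute log2 fold change of at least 1, and an adjusted p under 0.01. The list tests were repeated with an estimated correlation and with fry, and the position with all genes and with genes chosen from separate reference libraries. Chosen after seeing the data were array weights per group, exclusion of X and Y genes, a term for a library class set by RNAs without a poly-A tail, exclusion of such symbols, subtraction of a fibroblast share, and an ES library of its own for each kind of clone. Other tools were Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.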

Results

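Gene expression was measured in 8 libraries: a pair of 3F+IL6 iPS clones, a pair of 4F iPS clones, each clone derived separately, and biological duplicates of D3-GFP ES cells and of MEF, the fibroblasts of the mouse embryo. The estimated depth was 11800000 to 18200000 reads per library, and 13200 genes entered the tests. The first 3 principal components held 74.1%, 21.1% and 2.3% of the variance. On the third, 3F+IL6 clone 2 stood apart, at 30.4 against 2.77 for clone 1, −16.4 and −13.6 for the 4F clones and −3.65 to 2.47 for the ES and MEF libraries. Replicates were not equally close. Over genes with at least 100 estimated reads, the median chi-square between the 2 libraries of a group was 1.44 times its expected value for ES, 1.2 times for MEF, 3.62 times for 4F and 15.7 times for 3F+IL6. Pearson correlations across genes within these pairs were 0.9946, 0.9964, 0.9935 and 0.9841 in the same order. Between 3F+IL6 and 4F clones they ran from 0.977 to 0.989. At least 1 3F+IL6 clone was therefore closer to a 4F clone than to the other 3F+IL6 clone. Each pair differed by more than sampling noise, so no pair was treated as a single library deposited again. That the libraries of a group are separate replicates rests on the labels.

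The 3F+IL6 clones were made with Oct4, Klf4 and Sox2 and given IL6; 4F is the usual name for these factors together with c-Myc. The comparison asks how the transcriptomes of these kinds of clone differ. The set of factors and IL6 change together between the kinds, so their effects cannot be told apart here. The X-linked kinase gene Pim2 (chromosome X, 7878262 to 7883432) was at 105 ± 5.25 RPKM (SD, n = 2) in 3F+IL6 and 43.4 ± 0.45 in 4F clones. That is a log2 difference of 1.25 (SE 0.06; limma adjusted p = 0.0012). Of 12 genes of the primed pluripotent state, limma called 5 higher in 3F+IL6 clones and 7 were not called. The 5 were the de novo DNA methyltransferase genes Dnmt3a (chromosome 12, 3806007 to 3914443) and Dnmt3b (chromosome 2, 153649450 to 153687730) and the transcription factor genes Otx2, Pou3f1 and Zic2. Tfcp2l1, a transcription factor gene of naive pluripotency, was lower, at 17.9 ± 0.696 against 27.1 ± 0.317 RPKM. The calls of these 5 genes and of Tfcp2l1 were lost in the fit of only the 4 samples compared, without ES 1, ES 2, 4F clone 1, 4F clone 2, MEF 1 or MEF 2, and with array weights or the library class as a term, both chosen after seeing the data. In each of these, limma called 0 of the 5 primed genes and 5 had an unadjusted p under 0.05. With a pseudocount of 0.1 or the replicate number as a block only Dnmt3a of the 5 was called, and with no filter Dnmt3b was not. The block also ended the Tfcp2l1 call. The Pim2 call was lost without 4F clone 2 (1.26) and with the library class.

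Of the 12 primed pluripotency genes measured, 5 rose in 3F+IL6 relative to 4F over all genes tested, 0 fell, and 10 rose adjusted over the list alone. Their log2 differences were 0.90 for Dnmt3a, 0.96 for Dnmt3b, 0.75 for Otx2, 1.08 for Pou3f1 and 1.04 for Zic2. The list was called by camera (adjusted p = 1.1e-07; adjusted p = 0.4 with an estimated correlation). Among 17 interferon response genes, 3 rose and 0 fell, with 8 higher adjusted over the list alone. The 3 were Isg15 (1.5), which encodes a ubiquitin-like protein, Oasl2 (0.87) and Rtp4 (1.02). Usp18 had a difference of 1.01 (adjusted p = 0.051) and was not called. camera gave this list an adjusted p = 1.5e-05, with adjusted p = 0.57 with an estimated correlation. Of 29 fibroblast and mesenchymal genes, Vim, the intermediate filament gene vimentin, rose (0.39). Adjusted over the list alone, 5 were higher, and Dcn had a difference of 0.95 (adjusted p = 0.061). camera called the list higher (adjusted p = 0.00016; adjusted p = 0.7 with an estimated correlation). Of 21 other imprinted genes, Grb10, a growth factor receptor adaptor gene, rose by 1.05, and 9 were higher adjusted over the list alone (camera adjusted p = 0.00031; adjusted p = 0.4 with an estimated correlation). Over the fixed lists limma called 18 members between the kinds of clone, and 0 of them in the fit of only the 4 samples compared or without any single ES, 4F or MEF library, where 17 (without ES 1 or ES 2) or 18 had an unadjusted p under 0.05. With a pseudocount of 0.1, 7 of the 18 were called, and Isg15, Oasl2, Rtp4, Vim and Grb10 were not. With no filter 10 were called, and of these genes only Oasl2. The replicate number as a block left 4 of the 18, and of these genes again only Oasl2. The Vim call was also lost with median centring, with limma without trend and after subtraction of a fibroblast share, the last chosen after seeing the data.

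Other lists were lower in 3F+IL6 clones by camera. Of 17 p53 target and senescence genes, Pmaip1, which encodes the pro-apoptotic protein Noxa, fell by 0.59, and 6 were lower adjusted over the list alone (camera adjusted p = 5e-05; adjusted p = 0.55 with an estimated correlation). Of 101 ribosomal protein symbols, Rpl22l1 alone was called, at −0.40, over all genes and also adjusted over the list alone. The median of the list was −0.12, and −0.03 with quantile normalization (camera adjusted p = 6.5e-11; adjusted p = 0.57 with an estimated correlation). Of 17 germline genes, limma called 0, over all genes tested and adjusted over the list alone, and 6 had an unadjusted p under 0.05 (camera adjusted p = 0.018; adjusted p = 0.57 with an estimated correlation). Replication-dependent histone transcripts mostly lack a poly-A tail, and their list had a median of −1.17 over 47 members. Hist1h3i was the member called, over all genes tested and adjusted over the list alone, and was listed at 0 in both 3F+IL6 clones against 6.26 ± 3.86 RPKM in 4F (camera adjusted p = 3.5e-09; adjusted p = 0.57 with an estimated correlation). By camera, the germline call was lost without 3F+IL6 clone 1 (adjusted p = 0.18), without 4F clone 2 (0.053) and with a mean of at least 5 (0.22), which also ended the histone call (0.11). The fibroblast call was lost without 3F+IL6 clone 2 (0.076). The limma calls of Pmaip1, Rpl22l1 and Hist1h3i were lost in the fit of only the 4 samples compared and without any single ES, 4F or MEF library. That of Pmaip1 was also lost with a pseudocount of 0.1, no filter or the replicate number as a block, and that of Hist1h3i with no filter.

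The sum of Rn45s, Rpph1 and Rmrp, RNAs that also lack a poly-A tail, moved with this comparison. It was 64.9 and 60.8 RPKM in the 3F+IL6 clones and 610.4 and 596.1 in the 4F clones. It also split the replicates of the references, with 89.8 and 704.1 in ES cells and 46.5 and 267.5 in MEF. The Cajal body RNA Scarna10 was listed at 0 in both 3F+IL6 clones and was at 9.56 ± 3.1 RPKM in 4F. The small nucleolar RNAs Snord95 (−2.21) and Snord96a (−1.02) were lower as well. Of 178 symbols of these RNA classes, 9 were called between the kinds of clone, 8 of them lower in 3F+IL6, and the 168 other calls were of other genes.

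**Figure D1:**
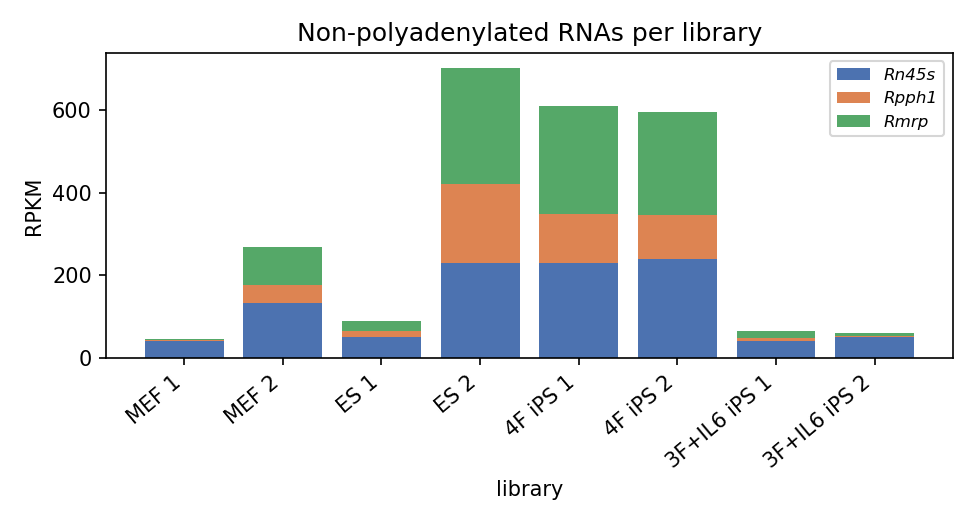
Stacked bars give the RPKM of Rn45s, Rpph1 and Rmrp in each of the 8 libraries, with the libraries on the x axis. The sum runs from 46.5 in MEF 1 to 704.1 in ES 2 and is 610.4 and 596.1 in the 4F clones against 64.9 and 60.8 in the 3F+IL6 clones.

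Myc itself (chromosome 15, 61985391 to 61990374) was at 5.09 and 16.8 RPKM in the 3F+IL6 clones, 53.8 ± 1.13 in 4F, 20.7 ± 0.302 in ES cells and 62.4 ± 0.00757 in MEF. Its difference between the kinds of clone was −2.39 (SE 0.42; limma adjusted p = 0.051) and did not pass the threshold, but did with median centring (−2.43), with quantile normalization (−2.42), with the stricter filter, and without 3F+IL6 clone 1 (−1.62) or clone 2 (−3.17). Leaving out a 3F+IL6 clone removes the spread of that pair from the shared estimate. Calls gained that way, here and in the comparisons below, are therefore no support. Reads from a delivered factor and from the gene of the cell are not separated in these values. The related Mycn was at 60 ± 23.9 RPKM in 3F+IL6 and 27.6 ± 0.629 in 4F (1.03; limma adjusted p = 0.075), and was called without 3F+IL6 clone 1 (1.44) or clone 2 (0.62). In the MYC family list of 7 genes limma called 0, with 3 at an unadjusted p under 0.05, and adjusted over the list alone 1 was higher and 1 lower (camera adjusted p = 0.46; adjusted p = 0.7 with an estimated correlation). Of 31 MYC target genes limma called 0, over all genes tested and adjusted over the list alone, and 5 had an unadjusted p under 0.05. Their median difference was 0.01, or −0.03 with median centring, while camera pointed down (adjusted p = 0.85; adjusted p = 0.97 with an estimated correlation). Pou5f1 (0.05), Sox2 (0.01, −0.03 with median centring) and Klf4 (−0.39) did not differ past the threshold either. Without 3F+IL6 clone 1 Klf4 was at 0.17, and without clone 2 at −0.95 and called; Sox2 was at −0.08 without 3F+IL6 clone 2 and −0.05 without 4F clone 1.

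The IL6 and LIF receptor pathway held 17 measured genes, of which limma called 0 between the kinds of clone and 5 had an unadjusted p under 0.05. Adjusted over the list alone, 1 was higher and 2 were lower. The median difference was −0.07 and the mean 0.04, and camera gave an adjusted p = 0.47 (adjusted p = 0.7 with an estimated correlation). The shared receptor subunit gene Il6st was at 12.3 ± 0.99 RPKM in 3F+IL6 and 9.89 ± 0.339 in 4F, Lifr at 2.81 ± 0.0416 and 3.98 ± 0.148, and Stat3 at 22.3 ± 0.961 and 25.5 ± 1.23. Socs3, a feedback inhibitor of the pathway, was at 42.2 ± 5.09 and 53.7 ± 4.12, and Il6 at 2.82 ± 1.22 and 1.32 ± 0.975. Of 15 STAT3 targets, Tfcp2l1 fell by 0.57 and no other was called over all genes tested, with 1 higher and 3 lower adjusted over the list alone (median −0.07, mean 0.06; camera adjusted p = 0.61; adjusted p = 0.87 with an estimated correlation). Of 28 pluripotency network genes, 1 fell, again Tfcp2l1, and adjusted over the list alone 1 was higher and 2 lower (camera adjusted p = 0.53; adjusted p = 0.85 with an estimated correlation).

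**Figure D2:**
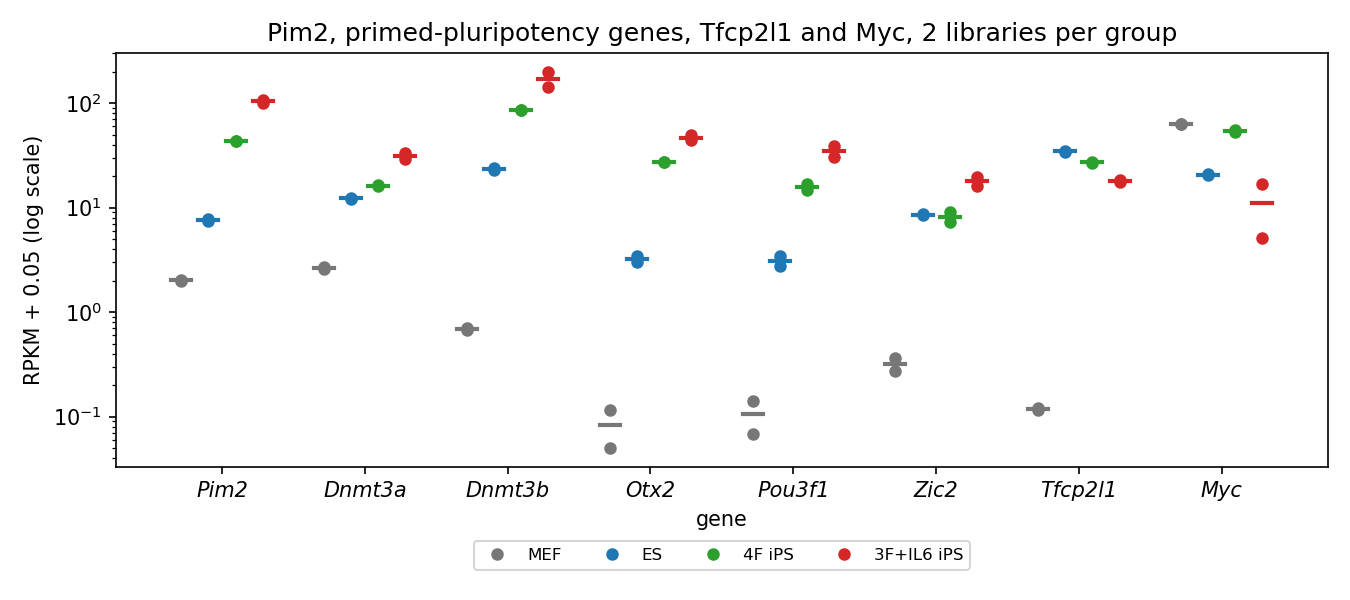
Points are RPKM + 0.05 on a log axis for 8 genes in each library and bars are group means of 2 libraries. Pim2 lies at 105 in 3F+IL6 and 43.4 in 4F clones, and Myc at 5.09 and 16.8 in the 3F+IL6 clones.

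In all, 177 genes were called between the kinds of clone, 102 higher and 75 lower in 3F+IL6, and 3198 had an unadjusted p under 0.05. The largest increases by the fixed rule were Isg15, Mmp3 (1.29), a matrix metalloproteinase gene, Pim2, Vrtn (1.15), Pou3f1 and Grb10. Besides the RNAs without a poly-A tail, the largest decreases were Myl4 (−1.46), a myosin light chain gene, and Fkbp6 (−1.09). The count rests on a spread shared by groups of unequal spread. With a spread pooled over ES and MEF and another pooled over the kinds of clone, 32.5% of simulated calls were false. That simulation changed 200 genes, so its share does not carry over to the 177 calls. The fit of only the 4 samples compared called 12 genes, of which 11 lack a poly-A tail and the other is Pim2. Without either ES library the count was 8, without either MEF library 7, without 4F clone 1 or clone 2 it was 3 or 1, and without 3F+IL6 clone 1 or clone 2 it was 4782 or 831. With the library class, a term chosen after seeing the data, it was 1.

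Comparison of 3F+IL6 clones with ES cells asks how far clones made without c-Myc resemble the reference pluripotent line. Pou5f1 (chromosome 17, 35506018 to 35510772), the gene of Oct4, was at 1010 ± 8.22 RPKM in 3F+IL6 and 946 ± 10.3 in ES cells, and Sox2 at 172 ± 14 and 154 ± 7.67; neither was called. Klf4 fell by 0.88 (SE 0.3; adjusted p = 0.039), a call lost with quantile normalization (−0.81), with no filter, in the fit of only the 4 samples compared, and without ES 1 (−0.89), ES 2 (−0.87) or any single 4F or MEF library (−0.88 in each). Myc had a difference of −1.05 (limma adjusted p = 0.062), which was called with median centring (−1.08) and without 3F+IL6 clone 1 (−0.28) or clone 2 (−1.83). The collagen gene Col1a1 was higher in the clones (61.5 ± 14.2 against 1.63 ± 0.0477 RPKM), as were Lox, a collagen cross-linking enzyme gene, and Dcn. Dazl, an RNA-binding protein gene of germ cells, was lower, at 2.54 ± 1.21 against 94.9 ± 0.801 RPKM.

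Of 29 fibroblast and mesenchymal genes, 25 rose relative to ES cells and 3 fell, the same numbers adjusted over the list alone, with log2 differences of 4.56 for Lox, 3.60 for Thbs1, 4.55 for Col1a1 and 5.67 for Dcn (camera adjusted p = 2.6e-07; adjusted p = 0.57 with an estimated correlation). Of 15 epithelial genes, 14 rose and 0 fell, also adjusted over the list alone, among them the splicing regulator gene Esrp1 (3.94), the claudin gene Cldn6 (3.14) and Grhl2 (2.88) (camera adjusted p = 1.1e-06; adjusted p = 0.4 with an estimated correlation). Of 12 primed pluripotency genes, 11 rose and 1 fell, also adjusted over the list alone, with Otx2 at 3.52 and Dnmt3b at 2.79 (camera adjusted p = 5.8e-05; adjusted p = 0.4 with an estimated correlation). Of 17 interferon response genes, 16 rose and 1 fell by either adjustment, which is to say over all genes tested or adjusted over the list alone, with Oasl2 at 3.21 and Bst2 at 3.30 (camera adjusted p = 1.4e-05; adjusted p = 0.57 with an estimated correlation).

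Of 17 p53 target and senescence genes, 14 rose and 0 fell, also adjusted over the list alone, with Cdkn1a, the gene of the cell cycle inhibitor p21, at 2.47 and Pmaip1 at 1.76 (camera adjusted p = 0.00019; adjusted p = 0.57 with an estimated correlation). Of 21 glycolysis genes, 15 rose and 2 fell, also adjusted over the list alone, with the lactate transporter gene Slc16a3 at 3.47 and the lactate dehydrogenase gene Ldha at 2.17 (camera adjusted p = 0.0018; adjusted p = 0.71 with an estimated correlation). Of 101 ribosomal protein symbols, 56 rose and 7 fell, also adjusted over the list alone, but the median of 0.19 was 0.00 with quantile normalization (camera adjusted p = 0.0011; adjusted p = 0.72 with an estimated correlation). The members with the smallest p included the kinase genes Rps6kl1 (2.00) and Rps6ka1 (1.33) and the pseudogene Rps15a-ps6 (−2.28). Of 17 germline genes, 12 fell and 3 rose, also adjusted over the list alone, with Stk31 at −2.19, Taf7l at −2.85 and Dazl at −4.80 (camera adjusted p = 0.0038; adjusted p = 0.55 with an estimated correlation). Of 7 ectoderm and neural genes, 5 fell and 0 rose, also adjusted over the list alone, with the transcription factor genes Pax6 at −2.66 and Sox1 at −1.61 (camera adjusted p = 0.014; adjusted p = 0.53 with an estimated correlation).

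Of 28 pluripotency network genes, 7 rose and 13 fell (7 and 14 adjusted over the list alone), with Dppa3 at 3.06, Fgf4 at 1.5 and Fbxo15 at −1.54, and camera did not call the list (adjusted p = 0.23; adjusted p = 0.71 with an estimated correlation). Among 31 MYC targets, 6 rose and 10 fell, also adjusted over the list alone; the median was −0.08, the mean 0.01 (camera adjusted p = 0.53; adjusted p = 0.91 with an estimated correlation). In the imprinted Dlk1-Dio3 domain 4 of 5 genes rose, also adjusted over the list alone, with the non-coding RNA genes Rian at 2.99 and Meg3 at 1.54 (camera adjusted p = 0.14; adjusted p = 0.7 with an estimated correlation). Dlk1 was called at 0.54, a call lost with quantile normalization (0.11). Rian was at 40.1 and 15.3 RPKM in the 3F+IL6 clones and 2.27 ± 0.0321 in ES cells. Of 6 sex chromosome genes, 4 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.035; adjusted p = 0.53 with an estimated correlation). The Y-linked Eif2s3y was at 0.505 ± 0.238 RPKM against 36.9 ± 0.0539, Ddx3y fell by 3.25 and Uty by 2.17, and Xist, the RNA of X inactivation, rose to 1.23 ± 0.00645 from 0.0339 ± 0.0334 RPKM. camera's call of the sex chromosome list was lost without ES 1 or ES 2 (adjusted p = 0.061 in each), 3F+IL6 clone 2 (0.068) or either 4F clone (0.053). The neural call was lost with no filter (0.067) or a mean of at least 5 (0.091), the germline call with the latter (0.087) and the ribosomal call with quantile normalization (0.72).

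limma called 8374 genes between 3F+IL6 clones and ES cells, 4371 higher and 4003 lower, and 2192 with an absolute log2 difference of at least 1. The largest increases by the fixed rule were AI662270, Bgn, Mmp3, Dcn, Snurf and Plac8; Snurf was listed at 0 in both ES libraries and was at 43.5 ± 1.02 RPKM in the clones. The largest decreases were Stra8 (−4.90), a gene induced by retinoic acid in germ cells, Dazl, Eif2s3y, Enox1 (−4.44), Aard (−4.39) and Mras (−4.17). Strain and cell type change together here.

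The same question was asked of 4F clones. Pou5f1 (971 ± 45 RPKM) and Sox2 (171 ± 9) were not called against ES cells, nor was Klf4 (−0.48; limma adjusted p = 0.19), which was called in the fit of only the 4 samples compared and without either 3F+IL6 clone (−0.48 in each). With quantile normalization Pou5f1 was at −0.24. Myc was higher by 1.34 (SE 0.42; adjusted p = 0.025), a call lost when either ES library (1.35 and 1.33) or either 4F clone (1.36 and 1.32) was left out. Lox (4.39), Thbs1 (3.33), Col1a1 (4.31), Esrp1 (3.66), Cldn6 (3.11), Cdkn1a (2.76) and Pmaip1 (2.35) were higher, as in 3F+IL6 clones. The smooth muscle gene Tagln went the other way, at 22.7 ± 1.36 RPKM against 123 ± 3.52 in ES cells.

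Over all genes tested and, in brackets, adjusted over the list alone, the counts were 22 higher and 4 lower (24 and 4) of 29 fibroblast genes, 12 and 0 (12 and 0) of 15 epithelial genes, and 14 and 0 (14 and 0) of 17 p53 targets. camera called these lists with adjusted p = 6.1e-06, 3.2e-06 and 1.7e-05; with an estimated correlation the values were adjusted p = 0.64, 0.4 and 0.54. Of 12 primed pluripotency genes, 9 rose and 1 fell, also adjusted over the list alone, with Otx2 at 2.77 and Pou3f1 at 2.05 (camera adjusted p = 0.0041; adjusted p = 0.42 with an estimated correlation). Of 17 interferon response genes, 12 rose and 1 fell, also adjusted over the list alone, with Bst2 at 3.14 and Oasl2 at 2.34 (camera adjusted p = 0.00043; adjusted p = 0.57 with an estimated correlation). Of 21 glycolysis genes, 15 rose and 3 fell, also adjusted over the list alone, with Slc16a3 at 3.35 and the hexokinase gene Hk1 at 2.18 (camera adjusted p = 0.00091; adjusted p = 0.71 with an estimated correlation). Of 101 ribosomal protein symbols, 77 rose and 8 fell (79 and 9 adjusted over the list alone), with a median of 0.29 that was 0.02 with quantile normalization (camera adjusted p = 3.2e-07; adjusted p = 0.63 with an estimated correlation).

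Of 17 germline genes, 10 fell and 3 rose, also adjusted over the list alone, with Stk31 at −2.00, Dazl at −4.21 and Taf7l at −2.52 (camera adjusted p = 0.018; adjusted p = 0.57 with an estimated correlation). Of 7 ectoderm and neural genes, 5 fell and 0 rose, also adjusted over the list alone, with Pax6 at −2.69 and Sox1 at −1.75 (camera adjusted p = 0.013; adjusted p = 0.53 with an estimated correlation). Of 28 pluripotency network genes, 6 rose and 15 fell (7 and 15 adjusted over the list alone), with Dppa3 at 3.10, Fgf4 at 1.45 and Fbxo15 at −1.34 (camera adjusted p = 0.24; adjusted p = 0.71 with an estimated correlation). In the Dlk1-Dio3 domain 3 of 5 genes rose (4 adjusted over the list alone), Rian by 2.81, Meg3 by 1.62 and Dlk1 by 0.53, the last not called with quantile normalization (0.15); camera gave an adjusted p = 0.15 (adjusted p = 0.7 with an estimated correlation). Of 6 sex chromosome genes, 4 fell and 1 rose, also adjusted over the list alone, with Eif2s3y at −4.74, Ddx3y at −3.39, Uty at −2.13 and Xist at 0.91 (camera adjusted p = 0.044; adjusted p = 0.53 with an estimated correlation). camera's call of that list was lost without ES 1 (adjusted p = 0.067), ES 2 (0.07), 3F+IL6 clone 1 (0.07) or 2 (0.071) and 4F clone 2 (0.063), with a pseudocount of 0.1 (0.056) and with only the 4 samples compared (0.067). The neural call was lost with no filter (0.084) or a mean of at least 5 (0.076), the germline call with the latter (0.16) and the ribosomal call with quantile normalization (0.31).

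limma called 8866 genes between 4F clones and ES cells, 4442 higher and 4424 lower, and 2407 with an absolute log2 difference of at least 1. The largest increases by the fixed rule were AI662270 (5.79), Ndufa4l2 (5.52), Bgn (5.37), Snurf, Plac8 (5.21) and Ndrg1 (5.13), and the largest decreases Eif2s3y, Aard (−4.62), Enox1 (−4.45), Stra8 (−4.30), Dazl and Mras (−4.12). Against ES cells, 3809 genes were higher and 3621 lower in both kinds of clone, and 17 went in opposite directions. Independent lists of these sizes would share 1470.9 and 1341.6 genes, and 50 simulations of unchanged clones against the same ES libraries shared 0 on average, by limma at the same threshold. They called at most 2 genes in either comparison, so this 0 measures nothing of the overlap. The correlation of the fold changes across genes was 0.939 (0.503 simulated) and the covariance 0.693 (0.012 simulated). In a fit chosen after seeing the data, each kind of clone was set against an ES library of its own. No ES library was shared, and a lone ES sample was assumed to vary like the other groups. Both ES libraries are of the same line and strain, so the overlap still includes any difference that belongs to the ES line. With ES 1 for 3F+IL6 and ES 2 for 4F, 2948 genes were higher and 2689 lower in both, against 948.8 and 815.8 for independent lists, and the covariance was 0.689. With the ES libraries exchanged the values were 2943, 2668, 955.1, 813.5 and 0.672.

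Comparison with MEF asks how far the clones moved from the starting cell type. In 3F+IL6 clones Pou5f1 was at 1010 ± 8.22 RPKM against 1.88 ± 7.78e-05 in MEF, and Dppa5a, Tdgf1, Utf1 and Zfp42, genes of pluripotent cells, rose by 9.48, 8.31, 8.22 and 7.32. The apolipoprotein gene Apoe rose by 7.69. Acta2, the gene of smooth muscle actin, was at 16.8 ± 4.5 against 3530 ± 44.4 RPKM, and Actg2, Sdpr, Ankrd1 and Tagln were lower too, at −6.99, −6.46, −6.26 and −6.19. Sox2 (6.49) and Klf4 (1.01; adjusted p = 0.016) were higher and Myc lower (−2.60; adjusted p = 0.00077). The Klf4 call was lost in the fit of only the 4 samples compared and without either MEF library (1.04 and 0.99).

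All 28 pluripotency network genes rose, also adjusted over the list alone, with Dppa4 at 6.58 and Fgf4 at 6.48 (camera adjusted p = 4.7e-09; adjusted p = 0.4 with an estimated correlation). All 15 epithelial genes rose, also adjusted over the list alone, with the adhesion genes Cdh1 (6.71) and Epcam (7.11) and Cldn6 at 6.61 (camera adjusted p = 1.3e-05; adjusted p = 0.4 with an estimated correlation). Of 29 fibroblast genes, 26 fell and 2 rose, also adjusted over the list alone, with Thbs1 at −5.72 and Vim at −4.03 (camera adjusted p = 1e-09; adjusted p = 0.57 with an estimated correlation). Of 31 Hox genes, which pattern the body axis, 30 fell and 0 rose, also adjusted over the list alone, with Hoxc10 at −3.14 and Hoxa10 at −2.50 (camera adjusted p = 6.5e-11; adjusted p = 0.42 with an estimated correlation). All 20 cell cycle genes rose, also adjusted over the list alone, with the replication helicase genes Mcm2 at 2.29 and Mcm3 at 2.09 and the mitotic checkpoint gene Bub1b at 2.18 (camera adjusted p = 1.2e-05; adjusted p = 0.53 with an estimated correlation).

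Of 21 glycolysis genes, 20 rose and 0 fell, also adjusted over the list alone, with Pdk1 at 4.55 and the glucose transporter gene Slc2a3 at 6.36 (camera adjusted p = 0.0011; adjusted p = 0.71 with an estimated correlation). Of 31 MYC targets, 23 rose and 2 fell, also adjusted over the list alone, with Fbl at 1.03, Odc1 at 1.32 and Npm1 at 1.18 (camera adjusted p = 0.018; adjusted p = 0.72 with an estimated correlation). All 5 Dlk1-Dio3 genes fell, also adjusted over the list alone, with Dlk1 at −3.43, Meg3 at −2.70 and Rian at −2.20 (camera adjusted p = 0.028; adjusted p = 0.57 with an estimated correlation). Of 17 germline genes, 15 rose and 1 fell, also adjusted over the list alone, with Mael at 4.10 and the meiotic gene Sycp3 at 4.57 (camera adjusted p = 0.0028; adjusted p = 0.54 with an estimated correlation). Primed pluripotency genes (11 of 12 higher, 0 lower) and ribosomal protein symbols (94 of 101 higher, 5 lower) rose too, with the same counts adjusted over the list alone; camera gave adjusted p = 0.00084 and 5.3e-09, and adjusted p = 0.4 and 0.57 with an estimated correlation. The Dlk1-Dio3 call by camera was lost with quantile normalization (adjusted p = 0.06) and without MEF 1 (0.098) or MEF 2 (0.099).

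limma called 10832 genes between 3F+IL6 clones and MEF, 6526 higher and 4306 lower, and 5513 with an absolute log2 difference of at least 1. The median of all genes was 0.263, which median centring lowered to 0.149 and quantile normalization to 0.062, so small increases are read against that shift. Of 4F clones against MEF, 11036 genes were called, 6498 higher and 4538 lower, with Dppa5a at 9.88, Pou5f1 at 8.40, Sox2 at 6.49, Klf4 at 1.40, Cdh1 at 6.60, Acta2 at −8.01, Vim at −4.42, Hoxc10 at −3.26 and Rian at −2.38. Myc was at −0.21 (limma adjusted p = 0.65) and was not called, except without 3F+IL6 clone 1 or clone 2 and in the fit of only the 4 samples compared (−0.21 in each). Of ES cells against MEF, 10787 genes were called, 6560 higher and 4227 lower, with Dppa5a at 9.27, Pou5f1 at 8.36, Zfp42 at 8.44, Sox2 at 6.34, Klf4 at 1.89, Cdh1 at 6.05, Epcam at 4.97, Acta2 at −9.44, Rian at −5.19 and Myc at −1.55. The median of all genes was 0.248 and 0.271 in these comparisons.

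Of the lists in 4F clones and ES cells against MEF, all 28 pluripotency network genes rose in both comparisons, as did 15 and 14 of 15 epithelial genes, 20 and 18 of 20 cell cycle genes, 16 and 15 of 17 germline genes and 22 and 25 of 31 MYC targets. Of the fibroblast list 27 and 29 of 29 fell, of the Hox genes 30 of 31 in each, and of the Dlk1-Dio3 genes all 5 in each, and these counts also held adjusted over the list alone. In 4F clones all 21 glycolysis genes rose. camera called all of these lists, with adjusted p from 2.3e-10 (fibroblast) to 0.033 (Dlk1-Dio3) in 4F clones and from 4.6e-13 (fibroblast) to 0.012 (Dlk1-Dio3) in ES cells. With an estimated correlation these lists had adjusted p = 0.4 to 0.73 in 4F clones and 0.4 to 0.71 in ES cells. camera also called ribosomal protein symbols in both (adjusted p = 2.1e-09 and 3.7e-07; adjusted p = 0.57 and 0.63 with an estimated correlation), primed pluripotency genes in 4F clones (adjusted p = 0.004; adjusted p = 0.42 with an estimated correlation) and immediate early genes, lower in ES cells (adjusted p = 0.011; adjusted p = 0.53 with an estimated correlation). Over all genes tested and adjusted over the list alone, 91 of 101 ribosomal symbols were higher and 5 lower in 4F clones, and 89 and 2 in ES cells. The counts were 11 and 1 of 12 primed genes in 4F clones, and 4 and 12 of 17 immediate early genes in ES cells, by either adjustment. In 4F clones camera's call of Dlk1-Dio3 was lost without either MEF library (adjusted p = 0.1 in each), with median centring (0.05), quantile normalization (0.062) or a mean of at least 5 (0.059), and that of MYC targets without MEF 1 (0.055), MEF 2 (0.058) or with a mean of at least 5 (0.063).

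**Figure D3:**
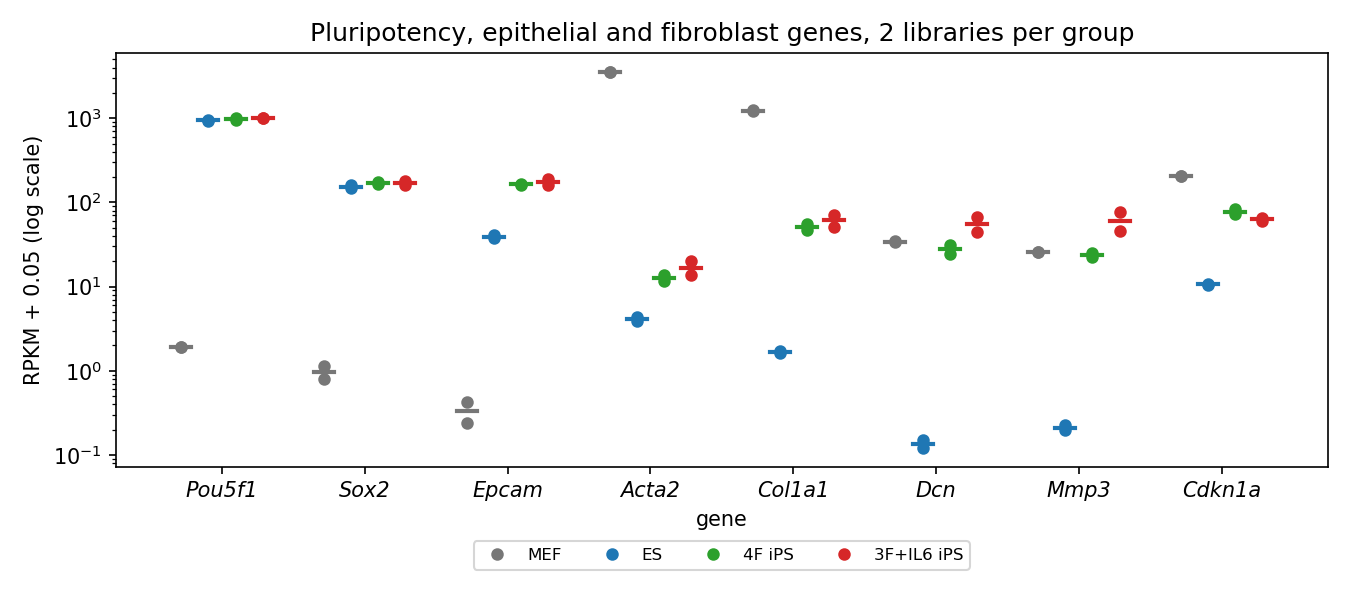
Points are RPKM + 0.05 on a log axis for 8 genes in each library and bars are group means of 2 libraries. Pou5f1 lies at 1010, 971 and 946 in 3F+IL6, 4F and ES libraries and at 1.88 in MEF, while Acta2 is at 3530 in MEF and 16.8 and 12.8 in the clones.

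Each clone was then placed on the line from the MEF mean (0%) to the ES mean (100%) over 5508 genes called between these references with an absolute log2 difference of at least 1. MEF and the clones are BALB/c and ES cells are not, so strain differences can hold the clones below 100%. The 3F+IL6 clones were at 79.7% and 77.2% (78.4 ± 1.8, SD, n = 2) and the 4F clones at 81.3% and 82.3% (81.8 ± 0.72, SD, n = 2). The difference of −3.34 percentage points gave p = 0.333 in a two-sided exact permutation test, the smallest p that this test allows for 2 against 2 samples, so it cannot reach 0.05 here.

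**Figure D4:**
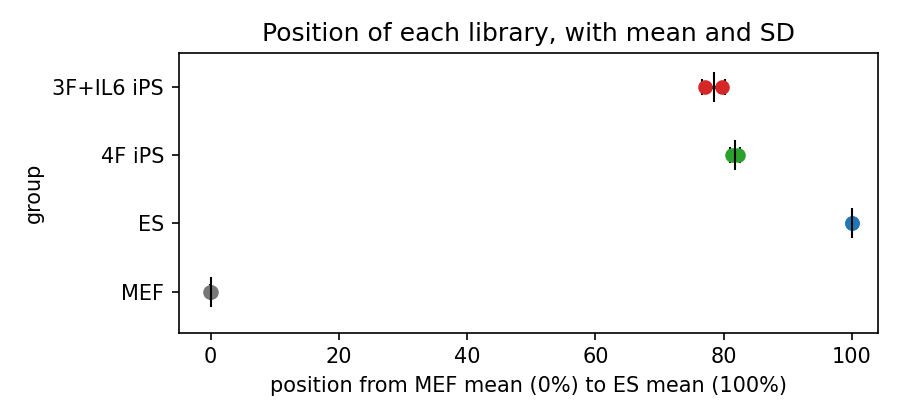
Points give the position of each library between the MEF mean at 0% and the ES mean at 100%, with the mean and SD of each group. The 3F+IL6 clones sit at 79.7% and 77.2% and the 4F clones at 81.3% and 82.3%. Strain and cell type change together along this line.

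Genes that fibroblasts express more than ES cells were not all at ES level in the clones. MEF and the clones are BALB/c and ES cells are not, so a gene higher in that strain would pass both comparisons too. Of 2414 genes called higher in MEF than in ES cells with a log2 difference of at least 1, 1307 were higher than ES in 3F+IL6 clones, 1137 in 4F clones and 1078 in both, while 286 and 377 were below ES. Between the kinds of clone, 23 of the genes kept above ES were higher in 3F+IL6 and 4 in 4F. No test of the difference between 1307 and 1137 was made, and the order turned without 3F+IL6 clone 2 (1280 and 1287) and with array weights per group (1141 and 1245), a setting chosen after seeing the data. Dcn was at 55.3 ± 15.9 RPKM in 3F+IL6, 27.7 ± 4.53 in 4F, 0.0858 ± 0.0214 in ES and 34.2 ± 0.675 in MEF, and Mmp3 at 60.8 ± 22.1, 23.5 ± 1.71, 0.162 ± 0.0199 and 25.5 ± 0.204. The numbers between the kinds were 661 and 154 without 3F+IL6 clone 1 and 105 and 25 without clone 2. They were 6 and 2 with no filter or with a pseudocount of 0.1, and 3 and 3 with the replicate number as a block. Quantile normalization gave 39 and 11. Array weights or the library class as a term, both chosen after seeing the data, gave 0 and 0. They were 1 and 0 without ES 1, 0 and 0 without ES 2 or either 4F clone, 0 and 2 without MEF 1, and 0 and 1 without MEF 2; at an unadjusted p under 0.05, limma had 3198 genes between the kinds over all 13200.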

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

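Of the tests weighed here, only the one on messenger RNA calls and the library class was set before its result was seen; the other tests were chosen afterwards. Of 522 members of the fixed lists, limma called 18 between the kinds of clone, and each difference is on the log2 scale, 3F+IL6 minus 4F. Higher in 3F+IL6 were Dnmt3a (0.90), Dnmt3b (0.96), Otx2 (0.75), Pou3f1 (1.08), Zic2 (1.04), Isg15 (1.5), Oasl2 (0.87), Rtp4 (1.02), Vim (0.39), Grb10 (1.05), Fosl1 (0.67) and Actc1 (0.58). Lower were Tfcp2l1 (−0.57), Pmaip1 (−0.59), Rpl22l1 (−0.40), Esx1 (−0.80) and Des (−0.71). Hist1h3i was listed at 0 in both 3F+IL6 clones, and its fitted difference of −2.75 on the log2(RPKM + 1) scale is no bound. Of the 18, limma called 0 in the fit of only the 4 samples compared, without any single ES, 4F or MEF library, and with array weights or the library class as a term, while 17 (without ES 1 or ES 2) or 18 kept their sign with an unadjusted p under 0.05. With a pseudocount of 0.1 it called 7, with no filter 10 and with the replicate number as a block 4. Leaving out an ES or MEF library, fitting only the 4 samples or weighting per group leaves each difference unchanged. A kept sign is no support in those settings.

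Of 29 fibroblast and mesenchymal genes, 25 were above ES in 3F+IL6 clones and 22 in 4F clones. Strain changes together with cell type in these comparisons. Over 40 genes abundant in MEF and nearly absent from ES cells, the clones sat at medians of 2.56% and 3.73% (3F+IL6) and 2.30% and 2.22% (4F) of the MEF level, with Acta2 at 0.385% and Bgn at 9.04% in 3F+IL6 clone 1. As the only source, admixed cells like the sequenced fibroblasts would bring these genes at a single share. The 95th percentile was at least 17.5 times the 5th in every clone, which argues against that. A smaller share of such cells beside another source stays open. A single admixed population of another profile stays open: 34 of the 40 genes were higher in 3F+IL6 clone 2 than in clone 1 (15 of 40 in the 4F pair), as a larger share in clone 2 would give, and the SD of that ratio, 17.4 times that of the MEF pair, decides nothing because clones are set against a nearly technical spread. Feeder cells of varying profile stay open as well, and with no feeder library used here, admixed cells of such kinds and expression by the clones cannot be told apart for these 40 genes.

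Y-linked RNA was nearly absent from all 4 clones, and X-linked RNA was higher than in ES cells. Loss of the Y chromosome from male cells would leave the X at the level of the autosomes, but the lowest X median of the clones against ES was 0.298 (496 genes), above every autosome median. Female cells with both X chromosomes active would show such an excess against ES and against MEF, and its smallest value over the highest autosome median was 0.073, which is consistent with that explanation. Xist was called higher and Tsix lower than in ES cells in both kinds of clone, which the X median does not weigh. MEF expressed Eif2s3y at 30.5 ± 1.14 RPKM, and the sex of the embryos is not given in the sources used here. The hypothesis therefore needs a test on DNA.

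The sum of Rn45s, Rpph1 and Rmrp, RNAs without a poly-A tail, was 9.6 times as large in 4F as in 3F+IL6 clones, and of 178 symbols of such classes limma called 8 lower in 3F+IL6 and 1 higher. In MEF the sum differed 5.75-fold between the replicates, so such a split can arise without a difference in factors or IL6. It cannot show whether the factors or IL6 had a part in the difference between the clones. Poly-A selection that differed between libraries needs such splits within groups, and ES 2 was 7.84 times ES 1, consistent with that explanation. The 4 libraries with a high sum include both 4F clones and the 4 with a low sum both 3F+IL6 clones. With this class as a term, 100% of the 168 other called genes kept their sign with an unadjusted p under 0.05. Their median fold ratio was 0.995, their median SE went from 0.0866 to 0.139, and limma then called 1 gene. This decides nothing about the split as a cause of these calls, because class and kind coincide in the clones. The term is set by the ES and MEF pairs alone, and calls favour genes with a small spread in those pairs.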

How the results depend on the processing

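Array weights, the library class term, the exclusions of symbols, the subtraction of a fibroblast share and the split of the ES libraries were chosen after seeing the data. The count of 177 genes between the kinds of clone was 23 with a log2 difference of at least 1, 5 at an adjusted p under 0.01, 315 with quantile normalization, 56 with a pseudocount of 0.1 and 12 with only the 4 samples compared. It was 5 with array weights, 1 with the library class as a term and 281 without RNAs that lack a poly-A tail; the other 6 settings gave 152 to 223. Leaving out 1 library gave 1 (4F clone 2) to 4782 (3F+IL6 clone 1), with 831 without 3F+IL6 clone 2, 3 without 4F clone 1, 8 without either ES library and 7 without either MEF library. By construction, leaving out a library removes its pair's spread from the shared estimate and assumes that the remaining sample varies like the other groups. Pim2 was called in 19 of the 21 settings that test it.

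With the replicate number as a block, 36 genes were called between the kinds, and of the fibroblast genes above ES 3 were higher in each kind. Of the 18 called members of the lists, 4 were called with it (Dnmt3a, Oasl2, Rpl22l1 and Hist1h3i), and 18 had an unadjusted p under 0.05. Deviations of same-numbered samples correlated at −0.055 to 0.214 across the 6 pairs of groups, so the numbers were not taken to pair the samples. ES 1 and MEF 1 did share a low sum of RNAs without a poly-A tail, and ES 2 and MEF 2 a high one, while the clones did not follow their numbers. By camera, the block ended the call of the sex chromosome list in 4F against ES (adjusted p = 0.055) and brought under the threshold glycolysis between the kinds (0.035, from 0.054) and interferon genes in ES against MEF (0.048, from 0.063). It changed no other list call.

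In the other comparisons a log2 difference of at least 1 left 2192 genes (3F+IL6 against ES), 2407 (4F against ES), 5513 (3F+IL6 against MEF), 5818 (4F against MEF) and 5508 (ES against MEF), because fewer genes can pass. The other 22 settings of each stayed within 1.5 times the count, at 5744 to 9240, 6163 to 9976, 7275 to 12496, 7391 to 12753 and 7351 to 12194. The overlap against ES was 1803 with that threshold and 5186 to 8554 otherwise. The fibroblast genes above ES were 786 (3F+IL6) and 727 (4F) with a mean of at least 5, 621 and 523 with that threshold, and 1043 to 1594 and 949 to 1463 otherwise.

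camera called 8, 10, 10, 11, 11 and 10 lists in the order 3F+IL6 against 4F, 3F+IL6 and 4F against ES, 3F+IL6 and 4F against MEF, and ES against MEF. With an estimated correlation it called 0 in each, while 16 of the 174 tests had an unadjusted p under 0.05. fry for change in either direction called 19, 27, 27, 28, 29 and 28, and fry for a single direction 21, 20, 25, 26 and 25 in the last 5. Between the kinds of clone, fry for a single direction did not call every list that camera called. It gave adjusted p = 0.15 for fibroblast, 0.099 for germline, 0.079 for ribosomal and 0.19 for histone genes. fry does not compare a list with other genes.

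The position of 4F clones was 81.8%, and 83.6% with quantile normalization, 82.8% with a mean of at least 5, and 80.4% to 82.4% when 1 library was left out, the lowest without MEF 1. That of 3F+IL6 clones was 78.4%. Subtraction of a fibroblast share gave 84.8% (3F+IL6) and 87.2% (4F), by construction, since part of the MEF profile is removed. The other settings gave 77.1% to 80.2% for 3F+IL6. The cause of the other moves was not tested.

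Differences that were not called changed sign as follows. Sox2 between the kinds was −0.03 with median centring and −0.08 to 0.09 when 1 library was left out. Klf4 between the kinds was −0.95 to 0.17 when 1 library was left out, and Pou5f1 against ES was −0.10 in 3F+IL6 and −0.24 in 4F with quantile normalization. Pou5f1 in 4F was −0.01 without 4F clone 1. The cause was not tested. Of the values of named genes between the kinds, 214 lost the call, 22 gained it and 356 stayed on their side. The depth of 11800000 to 18200000 reads limits genes near an RPKM of 1.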

Other observations

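The low-oxygen test was set before its result was seen; the cell type lists were planned. Markers of other cell types differed in part from ES cells. The macrophage gene Lyz2 was listed at 0 in both ES libraries and was at 23.4 ± 7.5 RPKM in 3F+IL6, 17.7 ± 2.06 in 4F and 3.17 ± 0.173 in MEF. Over all genes tested and adjusted over the list alone, 5 of 7 macrophage and blood genes were higher than ES and 1 lower in 3F+IL6, and 4 and 0 in 4F. camera did not call that list (adjusted p = 0.23 in each; adjusted p = 0.57 with an estimated correlation). Of 6 cartilage and bone genes, 4 rose and 0 fell in each kind by either adjustment, with the collagen gene Col2a1 at 1.60 and 1.40 (camera adjusted p = 0.23 and 0.15). Of 17 immediate early and stress genes, 8 rose and 3 fell in 3F+IL6, and 9 and 5 in 4F, with Jun at 2.31 and 1.91 and Ier3 at 3.49 and 3.29 (camera adjusted p = 0.26 and 0.41).

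Trophoblast genes went both ways, with Ascl2 at 2.70 and 3.02 and Esx1 at −1.95 and −1.15 in 3F+IL6 and 4F (camera adjusted p = 0.60 and 0.91). Primitive and visceral endoderm genes did so too, with Hnf4a at 1.51 and 1.54 and Gata6 at −0.97 and −0.92 (camera adjusted p = 0.61 and 0.97). Their median in 4F was −0.17 and their mean 0.06; the trophoblast median in 4F was −0.29 and the mean 0.24. The mesoderm gene Bmp4 fell by 1.73 and 2.01. Among endothelial genes Cldn5 rose by 1.31 and 1.56 while Esam fell by 1.02 and 0.87, and the list's median in 4F was 0.18 but −0.01 with quantile normalization.

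Low-oxygen targets may be higher in the clones, a hypothesis raised by Ndrg1, Ndufa4l2, Ddit4 and Bnip3, whose values had been seen. Ddit4 was at 7.29 ± 0.482 RPKM in ES, 242 ± 136 in 3F+IL6 and 266 ± 17.3 in 4F. Of 14 other measured targets, 10 were called higher than ES in both kinds of clone, between the bounds of 12 and 7 set beforehand, so the test decided nothing; 28.9% of all genes tested were higher in both. Egln3 (3.73 and 3.42), P4ha1 (2.60 and 3.07) and Adm (4.45 and 4.31) rose, while Ak4 (−1.97 and −1.53) and Kdm3a (−0.64 and −0.70) fell. In 3F+IL6 clone 2, 13 of the 14 were lower than in clone 1, with a median log2 difference of −0.82.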
